A study of Homo sapiens with 6 samples.

How the data were processed

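RNA sequencing values were deposited for 6 libraries labelled as HepG2, an established human liver tumour line. Per the genotype label, 3 libraries are WT, commonly short for wild type, and are called control here. Per the same label, 3 came from cells with knockdown of ZNF740 (also written ZFP740), a gene for a C2H2 zinc finger protein. Total RNA was extracted with a column kit, per the labels' protocols. The labels differ on the perturbation: the genotype label says knockdown, while the sample titles and the columns of the table carry the letters KO, commonly short for knockout. Groups and the word knockdown were taken from the genotype label, and replicate numbers from the titles. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these libraries, which may be technical.

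The single deposited table holds FPKM values (fragments per kilobase of feature, relative to the mapped fragments of the library) with 3 decimals, per the file headers, in 1 column per library. Each column was matched to a sample by the name in its title, and 0 value columns were left without a sample. The submitters' processing notes name HISAT2, a spliced aligner, and the human genome build GRCh38, without saying what each was used for. The counting tool, the annotation and any filter of features are not given in the sources used here.

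The table lists 86110 features. Each is named by the word Unigene and a 7-digit number, a style commonly used for assembled transcripts grouped into genes. The file does not pair these identifiers with gene names, coordinates or sequences. Of the 86110 identifiers, 0 matched a gene identifier or symbol in the human reference tables used here. The reference genome annotation was therefore not used. The level of ZNF740, which would have checked the labels, was not analysed here. For the same reason the 40 gene lists fixed before the data were examined (969 genes, of which 0 occur as identifiers), the list tests planned on them, and the levels of METTL3 and HIF1A were not analysed here. In the text below, "knockdown" stands for the libraries labelled so.

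Features were tested where FPKM was at least 1 in at least 3 of the 6 libraries, which left 19573. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1), with group as the only term and all 6 libraries in the fit. Values were not rescaled beyond the authors' FPKM. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low features. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. On simulated data with the 19573 features and 200 changed ones, the test recovered 84% of 2-fold and 100% of 4-fold changes, and 6.1% of its calls were false. The simulated noise was normal, independent between features and equal for all libraries, with variances drawn from limma's own fit. Far fewer features changed than the 10842 called in the data, so these figures are not error rates of the real calls. Library summaries were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

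The rule for named features, fixed before the data were examined, asked for the 10 largest changes in each direction among features with a gene symbol, an adjusted p under 0.05, no overlap between the groups and a mean of at least 5 FPKM in a group. No feature has a symbol, so the rule was applied without that condition and only 2 features per direction are named. The counts of abundant features, taken here as a mean of at least 1000 FPKM in a group, and of features seen in one group only were chosen after the data were seen.

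The table gives no counts and no library totals. Low FPKM values of different libraries stood in fixed ratios, as whole reads would give, and these ratios gave each library's depth relative to control replicate 1; ratios measured directly between other libraries differed from these by at most 0.01%. The inverse of the value of a single read was spaced evenly over 3831 features, as whole-number lengths would give. The strength of this spacing was 0.627, where 1 is perfect, against at most 0.047 in 5 repeats with the values jittered by up to 2%. The spacing implied 15000000 mapped fragments in control replicate 1. Such totals are inferred from the values and are no part of the table. Reads behind a feature were estimated at the shortest whole-number length, from 200 bases, that made each of its values above 0 in the group whole; a multiple of that length would give more reads.

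The replicate numbers are shared by both groups, so a fit with the number as a block was planned as an alternative. Deviations from the group means correlated at 0.008, 0.044 and -0.015 between libraries with the same number, under the 0.1 set for pairing, so the numbers were not taken to pair the libraries. Other alternatives were pseudocounts of 0.1 and 0.01, no filter beyond 1 value above 0, a filter of 5 FPKM in 3 libraries, TMM-type, median-ratio and quantile scaling, limma without the trend, limma with library quality weights, and leaving out each library in turn on the same 19573 features.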

Results

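RNA sequencing values were compared between 3 control libraries labelled WT and 3 labelled ZNF740 knockdown, all labelled as HepG2 hepatocellular carcinoma cells. Of the 86110 features in the table, 76589 were above 0 FPKM in at least 1 library and 9521 were at 0 in all 6. A control library showed 50525 to 53736 features above 0 and a knockdown library 49310 to 54120. The inferred depth was 15000000, 15100000 and 19600000 fragments in control replicates 1, 2 and 3, and 10700000, 14500000 and 13200000 in knockdown replicates 1, 2 and 3. Each knockdown library was thus shallower than each control library (exact permutation test of the mean relative depth, two-sided p = 0.1, the smallest possible).

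A small number of features held most of the signal in every library. The 100 most abundant features of a library took 88.5% ± 1.44 (SD, n = 3) of the summed FPKM in the control and 83.0% ± 1.44 (SD, n = 3) in the knockdown. The 2 groups did not overlap in this share, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The 10 most abundant took 25.5% ± 1.78 (SD, n = 3) in the control and 26.5% ± 1.03 (SD, n = 3) in the knockdown, a difference within the spread (exact permutation p = 0.5). At least 1 FPKM was reached by 16397 ± 1948 features (SD, n = 3) in the control and 19714 ± 192 (SD, n = 3) in the knockdown (exact permutation p = 0.1). Control replicate 1, with 18642 such features, stood apart from control replicates 2 and 3, with 15391 and 15157.

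The libraries separated by group. On log2(FPKM + 1), Pearson correlations across features were 0.962 to 0.968 among the control libraries and 0.965 to 0.968 among the knockdown libraries, against 0.794 to 0.803 between the groups. The Spearman correlations were 0.780 to 0.788, 0.798 to 0.804 and 0.596 to 0.615 in the same order. These are correlations across features, which are not independent replicates.

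Of the 19573 tested features, 10842 (55.4%) differed between knockdown and control. They passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 7226 of them higher and 3616 lower in the knockdown. The share depends on the features tested: it was 20% (15341 of 76589) with each feature above 0 in at least 1 library, and 60.1% (3808 of 6339) with a filter of 5 FPKM in 3 libraries. The 3 knockdown libraries lay wholly above the 3 control libraries for 7523 features and wholly below them for 4353, together 60.7% of those tested. For a single feature chance gives 10%. All features share the same libraries and are not independent, so the excess over 10% is no test of chance. A change of at least 2-fold on the log2(FPKM + 1) scale was found for 5527 features, of which 4586 were higher and 941 lower. The number lower depended on the pseudocount and the scaling: it was 1915 at a pseudocount of 0.1, 1950 at 0.01 and 2554 after quantile normalization, against 5811, 5875 and 3048 higher. For 5523 of these 5527 the groups did not overlap. The median standard error of a log2 fold change was 0.166.

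The split between higher and lower features depended on how the libraries were scaled. With the deposited FPKM, 66.6% of the called features were higher in the knockdown, and the median log2 fold change of all tested features was 0.10. Single control libraries moved this median: it was 0.216 without control replicate 1, 0.052 without control replicate 2 and 0.048 without control replicate 3, and 0.196 with library quality weights. The share of called features that were higher was 54.4% after TMM-type scaling, 56.6% after median-ratio scaling and 38.6% after quantile normalization, where the median was -0.01, 0.02 and -0.27. Among features changed at least 2-fold, 83% were higher with the deposited FPKM, and 78.2%, 79.6% and 54.4% under the same 3 scalings.

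**Figure D1:**
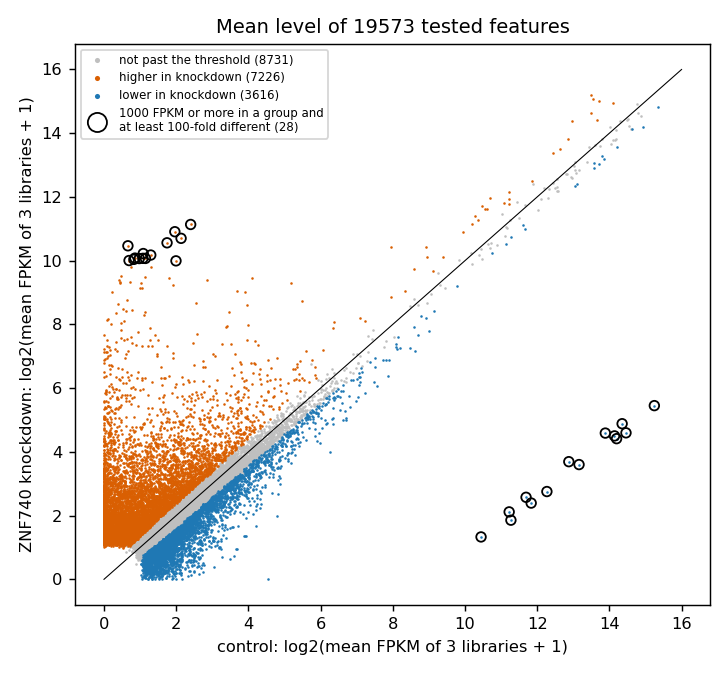
Mean level of each of the 19573 tested features, as log2(mean FPKM + 1) over the 3 control libraries (horizontal axis) and the 3 knockdown libraries (vertical axis), with the line of equal level. Orange and blue points are the 7226 features higher and the 3616 lower in the knockdown at an adjusted p under 0.05 (limma), grey points did not pass, and circles mark the 28 features of at least 1000 FPKM in a group that differed at least 100-fold, which form 2 clusters away from the line.

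Among the most abundant features, 28 stood at least 100-fold apart between the groups. A mean of at least 1000 FPKM in at least 1 group was reached by 129 features, and these held 88.0% to 90.9% of the summed FPKM of a control library and 83.6% to 86.1% of that of a knockdown library. Of the 129, 41 were higher and 30 lower in the knockdown at an adjusted p under 0.05 (limma). The group means differed at least 2-fold for 27 higher and 14 lower features. Of these, 14 in each direction differed at least 100-fold, and none lay between 10-fold and 100-fold. The equal numbers depend on the level taken as abundant, which was chosen after the data were seen: from 500 FPKM, 29 features were at least 100-fold higher and 14 lower. The groups overlapped for none of the 28 in these 6 libraries.

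The 14 abundant features that were at least 100-fold lower in the knockdown held 14.85%, 14.04% and 14.29% of the summed FPKM in control replicates 1, 2 and 3. They held 0.02%, 0.01% and 0.02% in knockdown replicates 1, 2 and 3. The 14 that were at least 100-fold higher held 1.79%, 1.48% and 1.75% in the knockdown libraries. The level left in the knockdown was 0.103% to 0.159% of the control level for each of the 14 lower features, and the control level was 0.041% to 0.293% of the knockdown level for the 14 higher ones.

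On the log2(FPKM + 1) scale of the test, the 2 largest fold changes in each direction belonged to these 28; for the higher features, the ratio of group means without the added 1 gives another order. Unigene0095054 had 22541 ± 3844 FPKM (SD, n = 3) in the control and 23.2 ± 1.17 (SD, n = 3) in the knockdown, a log2 fold change of -9.85 with a standard error of 0.17 and an adjusted p of 3.4e-14 in limma. Unigene0045860 had 38852 ± 4967 FPKM (SD, n = 3) in the control and 42.7 ± 6.39 (SD, n = 3) in the knockdown, a log2 fold change of -9.80 (adjusted p = 3.61e-14, limma). In the other direction, Unigene0086434 had 0.583 ± 0.384 FPKM (SD, n = 3) in the control and 1414 ± 35.3 (SD, n = 3) in the knockdown, a log2 fold change of 9.83 (adjusted p = 4.17e-14, limma). Unigene0053833 had 0.618 ± 0.435 FPKM (SD, n = 3) in the control and 1026 ± 45.0 (SD, n = 3) in the knockdown, a log2 fold change of 9.35 (adjusted p = 9.42e-14, limma). Each of the 4 changes kept its direction and its call under each alternative setting run.

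**Figure D2:**
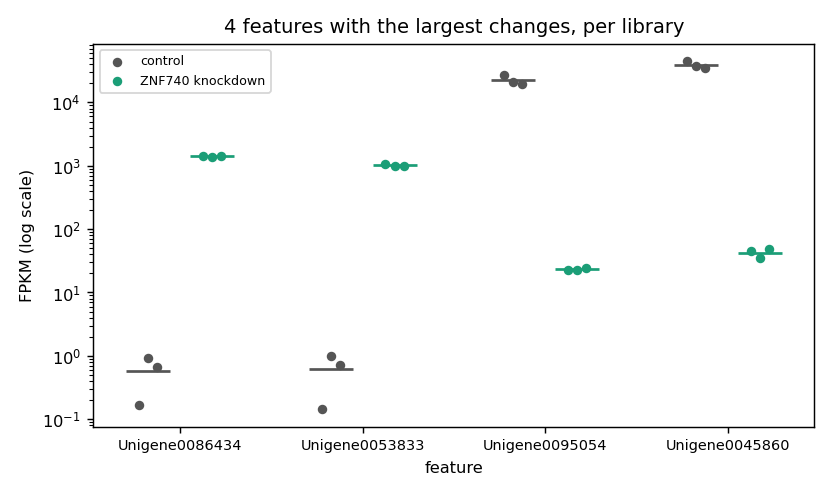
FPKM of the 4 named features in each library, on a log scale, with points for the 3 control (grey) and 3 knockdown (green) libraries and a line at each group mean. Unigene0086434 and Unigene0053833 lie under 1 FPKM in each control library, and Unigene0095054 and Unigene0045860 lie between 22.4 and 47.9 FPKM in the knockdown libraries.

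Changed features were found at each level of expression. Between 1 and 2 FPKM (mean of the 6 libraries), 35.6% of 6278 features were higher and 19.9% lower in the knockdown, and between 2 and 5 FPKM 34.7% of 6097 were higher and 16.4% lower. After TMM-type scaling these shares were 33.9% and 26.6%, and 34.3% and 28.8%. Between 5 and 20 FPKM, 33.5% of 4362 features were higher and 16.8% lower in the knockdown. Between 20 and 100 FPKM, 36.9% of 908 features were higher and 22.1% lower. In these 2 bands TMM-type scaling turned the order, with 34.8% higher and 37.5% lower in the first and 37.8% higher and 50.8% lower in the second. Between 100 and 1000 FPKM, 54.6% of 130 features were higher and 24.6% lower, and after TMM-type scaling 54.6% and 36.9%. At 1000 FPKM and above, 21.8% of 110 features were higher and 26.4% lower, and 19.1% and 30.9% after that scaling. Features with a mean below 1 FPKM could be tested only if at least 3 libraries reached 1 FPKM, so that band was enriched for differences by the filter itself.

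**Figure D3:**
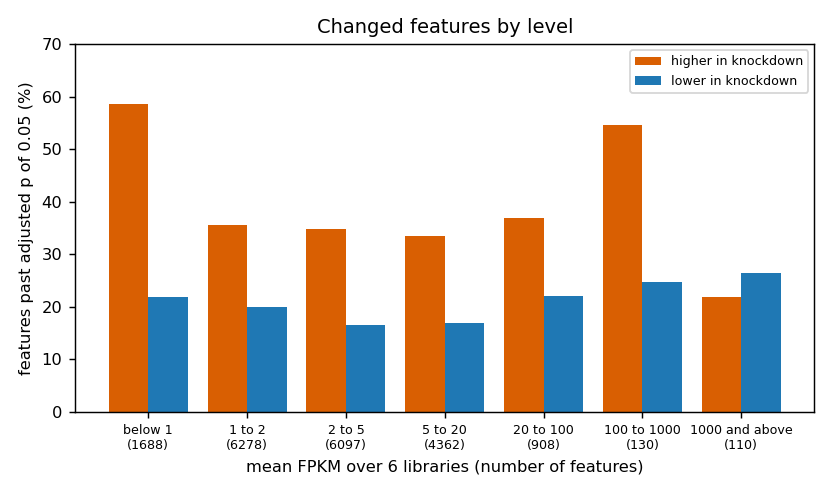
Percent of tested features that were higher (orange) or lower (blue) in the knockdown at an adjusted p under 0.05 (limma, deposited FPKM without rescaling), by the mean FPKM of the 6 libraries. The number of features in each band is under its bars; the share of higher features is 33.5% between 5 and 20 FPKM and 54.6% between 100 and 1000 FPKM.

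A further set of features was listed at 0 in each library of one group and above 0 in each library of the other. There were 2938 such features seen only in the knockdown and 1744 seen only in the control. The knockdown-only features had a median group mean of 0.73 FPKM; 1039 of them reached 1 FPKM, 134 reached 5 FPKM and 7 reached 50 FPKM. The control-only features had a median of 0.328 FPKM; 30 reached 1 FPKM and 1 reached 5 FPKM. Summed over the 3 libraries of the group, the estimated reads had a median of 13 for a knockdown-only and 7 for a control-only feature, and 1376 and 226 features had at least 15. A value of 0 in this table may be a low level below detection, in particular for the control-only features, since the knockdown libraries together had 0.773 times the depth of the control libraries.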

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

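The group counts, their directions and the 4 named features were recomputed under the alternatives; those for abundant and group-only features were chosen after seeing the data. With a filter of 5 FPKM in 3 libraries, 6339 features were tested and 3808 changed (2622 higher, 1186 lower, 2250 at least 2-fold), fewer because fewer were tested. The number of lower features was 5995 with TMM-type scaling, 5616 with median-ratio scaling and 9143 with quantile normalization, against 3616. Of the 10842 calls, 10660, 10726 and 9336 were still called under these scalings, in the same order. Quantile normalization turned the direction of 68 of the 10842. The other settings kept the number of changed features between 9570 and 15341. Leaving out control replicate 1, whose library quality weight was 0.22 against 1.06 to 2.01 for the others, gave 11466 changed features, 8331 higher and 3135 lower. The replicate numbers were not taken to pair the libraries, and the replicate block gave 11137 changed features against 10842. With at least 500 FPKM as abundant, 29 features were at least 100-fold higher in the knockdown against 14, and 14 were lower as before. Leaving out each library in turn gave 2458 to 2988 control-only features, against 1744, since fewer libraries have to meet the condition. The values over 1.5 times the count with all 6 were 2700 without control replicate 1, 2988 without control replicate 2, 2839 without knockdown replicate 2 and 2641 without knockdown replicate 3. The planned results on ZNF740, on the gene lists and on the correlation between genes of a list were not run, because the table names no genes. FPKM values hold no counts, so no count test was run, and the depth limits the features under 15 estimated reads.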

Other observations

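Of the tests below, the one on neighbouring group-only features and the bound of 5 FPKM for group-only features were fixed before their results were seen, and the 3 other scalings were planned; the other tests, and the bound applied to the scalings, were chosen after the results they bear on had been seen. Features next to each other in identifier order resembled each other. The rank correlation of their mean levels was 0.138, against at most 0.007 in 100 shuffles of the identifiers, and that of their log2 fold changes was 0.242 over 5890 neighbouring tested pairs, against at most 0.03. A knockdown-only feature had another knockdown-only feature next to it in 21.5% of cases, above the 7.97% at the upper end of 1000 shuffles. Among the 129 abundant features, 23.3% had another abundant feature within 2 places, against 3.1% at the upper end of the shuffles.

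The first pattern is the near loss of 28 abundant features from one group. Scaling cannot account for it, since the largest ratio of scaling factors between 2 libraries was 1.38. For the 14 features lower in the knockdown, the level left there followed the control level. It was 0.118% of it (median; 0.103% to 0.159%; upper over lower quartile 1.27-fold), with a rank correlation of 0.96 over a 27.9-fold span of control levels. A candidate explanation for this residual level is reads crossing between libraries at a fixed rate of about 0.1%, in which case the true differences are larger than those measured; a true residual expression in proportion was not tested. For the 14 higher features the control level was 0.108% (median; 0.041% to 0.293%) of the knockdown level, with quartiles 1.96-fold apart and a rank correlation of 0.49. Their knockdown levels spanned only 2.2-fold, and in control replicate 1 the percentage ran from 0.0118% to 0.3517%, so crossing reads stay open there. Outside the 28, 7 knockdown-only features reached 50 FPKM, the highest at 200.6, and were at 0 in each control library. Whether a rate of about 0.1% would have left visible reads for them was not tested. Whether the 28 are near-identical copies of one gene listed as neighbours cannot be told apart from other abundant features at this number: 35.7% had an abundant neighbour within 2 places, equal to the upper end of the shuffles.

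The second pattern is the 4682 features seen in one group only; another split of the 6 libraries gave at most 615. The tables argue against a difference in depth for the knockdown-only features, since the knockdown libraries were the shallower ones and 1376 features had at least 15 reads there. Of the control-only features, 226 had at least 15 reads in the control, where either side of another split of the 6 libraries had at most 8. Poisson counting allows 0.79 if each of the 86110 features is taken to have a true mean of 15 control reads. That value covers counting error only and leaves out the spread between libraries. The other 1518 had fewer than 15 reads. The study's own split differs in depth by 1.294-fold, and the 2 other splits of at least 1.2-fold (1.258 and 1.263) gave at most 490 such features on their deeper side. The excess over these splits argues against depth as the whole cause of the 1518. The splits mix both groups on each side, however, which can lower their counts. A part of the 1518 from depth stays open. The test of depth fixed beforehand would have set depth aside with at least 100 features of 5 FPKM or more in each direction. The knockdown-only features reached this number (134) and the control-only ones did not (1). As the test asked for it in each direction, depth was set aside by that test for neither set. For the control-only features, almost no feature at 5 FPKM is what depth would give. The read counts of the control-only features above, chosen afterwards, bear only on depth as their whole cause. Sequence variants of one gene assembled as neighbouring features would place opposite features side by side. The mark set beforehand for this, a share above the 4.66% at the upper end of the shuffles, was not reached. Of the knockdown-only features, 3.0% had a control-only neighbour, below the 3.27% at the lower end. The shuffles also broke up the grouping of like features, where 21.5% had a knockdown-only neighbour. Such grouping can itself lower the share of opposite neighbours, so this test cannot decide on neighbouring variants. Variants numbered far apart were not tested.

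The third pattern is the breadth of the difference. Under the 3 other scalings the number of changed features was at least 12949, so scaling did not create it. For the changed, higher, lower and at least 2-fold features, 1 of the 10 splits of the libraries, the study's own, gave as many (10842, 7226, 3616 and 5527). The highest of the other splits was 0 in each case. Each other split mixes both groups on both sides, so the group difference enters its spread and the 0 calls cannot speak on chance. The 10 splits are also too few for a share under 0.05. The knockdown itself, a difference between the cells or cultures other than ZNF740, and a library batch that follows the groups stay open, as the design holds nothing to separate them. Of the identifiers, 0 matched the human reference tables, which is consistent with a table of features other than annotated human genes, although the processing notes name GRCh38. Whether the table describes the labelled HepG2 libraries was not tested, since no feature has a sequence or a name.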
